A study of Oryza sativa with 6 samples.

How the data were processed

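RNA from leaves of 2-week-old rice seedlings was labelled with a 3-prime kit and hybridised to 6 Affymetrix rice arrays, per the labels' protocols. The arrays covered 2 genotypes, antisense-OsPDCD5 transgenic and nontransgenic Zhonghua 11, at 3 stages: before treatment, and 20 min and 3 h after transfer to dishes with 200 mM NaCl. Each of the 6 groups was 1 array made from 10 plants, and the labels named no seedlings moved without NaCl and none sampled untreated at the later times.

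The deposited values were log2 signals per probe set, computed by the authors with MAS5 per the submitters' processing notes. The MAS5 version and the scaling target were not given in the sources used here. Tested on the values, the lowest signal was 1 on the linear scale and the trimmed mean of the linear signal lay between 497.5 and 497.7 on every array, so the arrays had been scaled to a common mean. Detection calls were not used here. The table held 57258 rice probe sets and 123 control probe sets. Of the rice probe sets, 22436 had 1 gene in the platform annotation, 95 had several and 34727 had none. No gene was named from a probe set with several. Identifiers of all 22436 were found in the reference gene table (RefSeq genes of the rice reference assembly), which gave current names, and 3181 probe sets of 2447 genes carried a curated name. No probe set was tied to OsPDCD5 through these tables, and its signal is not analysed here.

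Signals were brought back to the linear scale, 16 was added and log2 was taken again, which damps differences near background. Where a signal lies below or near 16, the size of a log2 change therefore depends on that number. Probe sets with a mean over the 6 arrays below the median of all rice probe sets (log2 5.53) were left out, which kept 28629. An additive model of genotype and stage was fitted with lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The model left 2 residual degrees of freedom, to which the shared variance prior added 4.52, and the median residual SD was 0.20 on the log2 scale. The error is the deviation of single arrays from the additive pattern, which holds genotype differences in the salt response as well as noise. The p-values therefore say only whether a difference repeats over the pairs relative to those deviations, and measure no spread between replicate samples. Differences between the genotypes in their salt response take all residual degrees of freedom and were given as values with no test. The 20 min and 3 h contrasts share the same arrays from before treatment. Counts of probe sets changed at least 2-fold the same way in every pair of arrays were set beside the counts that independent pairs would give.

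For lists, 1 probe set stood for each gene, the one with the highest mean signal. Gene lists were tested with camera at its preset correlation of 0.01, adjusted over the lists within a contrast, and again with a correlation estimated from the residuals, which leaves that test with very few degrees of freedom. Of 31 lists with a gene past the filter, 27 had at least 5 and were set-tested. For single pairs of arrays, the median of a list was placed among 10000 random lists of the same size matched on mean signal. Each list's members were also counted as called over all probe sets and adjusted over the list alone.

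The functions were tested on simulated arrays of 28629 probe sets with 100 changed 2-fold and 100 changed 4-fold per contrast. With the real posterior variances, the 20 min contrast recovered 46 of the 2-fold and 86 of the 4-fold changes, and 10.2% of its calls were unchanged probe sets. The 3 h contrast recovered 49 and 93, with 22.0% of calls unchanged, and the genotype contrast recovered 57 and 92, with 14.9%. With variances drawn from the fitted prior instead, recovery of 2-fold and 4-fold changes was 9 and 60 at 20 min, 5 and 48 at 3 h, and 32 and 66 for genotype. Unchanged probe sets then made up 8.00%, 3.64% and 2.97% of the calls. The share of false calls in these runs thus lay above the nominal 5% in every contrast with the posterior variances. With those of the prior it did so at 20 min, where it rests on 6 false calls. Each setting was run 1 time with few changed probe sets, while 20.6% were called for genotype in the data. The shares therefore cannot be carried over to the real calls. Median estimates lay between 0.95 and 1.00 for a true log2 change of 1, and between 1.98 and 2.04 for 2.

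Named genes followed a rule: among probe sets past the filter with 1 gene, a curated name and the same sign in every pair, the 8 largest rises and the 8 largest falls past the threshold in each contrast. Where fewer passed, the places were filled by the largest changes judged by the smaller pair and are given as not past the threshold. Up to 4 members of a list with the largest change, and the 5 largest differences of response in each direction at each time, were named as well. The rule, the model, the filter, the lists by topic and most other settings were chosen before the data were examined. The rule asked for a description of function, and a curated symbol or synonym was taken in its place. The symbols that make up each list were matched after the annotation had been read and before any contrast was computed. A list holds only genes whose curated name matched, such as 6 WRKY and 8 NAC genes on the array. It may therefore not stand for its whole family. Scaling to the poly-A spike-ins and a fit without both 20 min arrays were chosen after seeing the data. Those other settings were other offsets, filters, scalings between arrays, no variance trend, no block, each array left out in turn, probe sets that can bind several transcripts left out, and the mean over all probe sets of a gene. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.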

Results

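Gene expression was measured in leaves of 2-week-old rice seedlings on 6 Affymetrix arrays. The seedlings were Zhonghua 11 carrying an antisense construct against OsPDCD5, a gene named for programmed cell death, or nontransgenic Zhonghua 11. Each genotype was sampled before treatment and after 20 min and 3 h in 200 mM NaCl, with 10 plants and 1 array per group. There were no replicate arrays, so a salt change rests on 2 pairs of arrays and a genotype difference on 3 pairs, and this number limits the precision of every value. The 3 pairs are stages of the same 2 genotypes and are not replicates of genotype. Any other lasting difference between the 2 sets of seedlings would repeat at each stage and cannot be told apart from the transgene. The median log2 MAS5 signal of the 57258 rice probe sets lay between 4.94 and 5.28 per array. Across the 28629 probe sets tested, pairs of arrays correlated at 0.902 to 0.972, a measure across genes, which are not independent replicates. The signal of OsPDCD5 itself is not analysed here, so the labels were not checked by the target gene. Changes in NaCl include the move to new dishes and the hours passed, since no group was moved or kept without salt.

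The 20 min comparison asks which leaf transcripts changed soon after seedlings entered NaCl. The transcription factor genes DREB1G, DREB1E and WRKY71 and the JAZ genes of jasmonate signalling named here rose. DREB1G (LOC4330306) rose by 5.41 ± 0.25 (log2 change ± SE, adjusted p = 0.00187), from a MAS5 signal of 110.0 to 3965 in nontransgenic and from 66.6 to 4724 in transgenic leaves. ABA8OX1 (LOC9269675), which encodes an abscisic acid 8′-hydroxylase, rose by 5.02 ± 0.51 (adjusted p = 0.0155). The jasmonate repressor genes JAZ13, JAZ12 and JAZ5 rose by 3.59, 3.26 and 2.25 (adjusted p = 0.0499, 0.0177 and 0.0131).

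WRKY71 rose by 2.59 ± 0.21 (adjusted p = 0.00937) and DREB1E by 2.64 ± 0.41 (adjusted p = 0.0491). The cellulose synthase gene CESA5 rose by 2.53 ± 0.24 and BC1L6, of the COBRA-like family, by 2.52 ± 0.28 (adjusted p = 0.0130 and 0.0222). Each of these genes was higher in both genotypes, as the naming rule required. Further rises were found for the aquaporin gene PIP2;7 (2.15), the calcium-dependent kinase genes CPK4 (2.07) and CPK20 (1.21), the gibberellin-responsive gene CIGR1 (1.67) and the heat shock factor gene HSFA3 (1.58). The protein phosphatase genes PP2C40 and PP2C61 rose by 1.53 and 1.04, the chitinase gene Cht6 by 1.43, the glutaredoxin gene GRXS9 by 1.13 and the trehalose-phosphate phosphatase gene TPP7 by 0.90. Among named genes, MYBAS1 and ITPK3 fell, by 1.08 ± 0.14 and 0.93 ± 0.12 (adjusted p = 0.0316 and 0.0308). Larger decreases that did not pass the threshold were those of the diterpenoid genes CPS2 (-3.02), KSL10 (-2.64) and CYP71Z7 (-2.43), with LAC24 (-2.75), ABCG48 (-2.49) and the isocitrate lyase gene ICL (-1.60). Their adjusted p lay between 0.137 and 0.463, and signals of CPS2, KSL10 and LAC24 at 20 min reached below 16. All 6 gained calls when scaled to the spike-ins (adjusted p from 8.51e-15 to 1.82e-06). Their changes moved little, while their SEs shrank, as for CYP71Z7 (-2.43 ± 0.94 before, -2.54 ± 0.30 after). These gains thus came from the estimated variance and add no evidence for the decreases. JAZ13 and DREB1E lost their calls with an offset of 1, no filter or quantile normalization (adjusted p up to 0.0855 and 0.138), and ITPK3 with no filter (0.0605).

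In the jasmonate and wounding list, 7 of 31 genes rose and none fell, and 14 rose when adjusted over the list alone. The list's median change was 0.52 (camera adjusted p = 1.07e-06), and 0.789 with an estimated correlation. In the single genotypes the median was 0.52 and 0.64, above the 95% range of random lists in each, outside which 12 and 11 of 27 lists lay. The WRKY genes with a curated name had a median of 1.12 over 6 genes (camera adjusted p = 0.00368), with 1 called and 2 adjusted over the list alone. Their median was 0.39 in nontransgenic and 1.74 in transgenic leaves, and WRKY24 (2.54) did not pass. NAC genes had a median of 0.50 over 7 genes (adjusted p = 0.00603), with 0 called over all and 3 adjusted over the list alone. Their largest values were ONAC004 at 0.90 and ONAC068 at 0.87. Chlorophyll synthesis genes had a median of 0.26 over 14 genes (adjusted p = 2.97e-04; 0.0516 when scaled to the spike-ins), with 0 called and 5 adjusted over the list alone, led by PORB at 0.91. With an estimated correlation the adjusted p of WRKY, NAC and chlorophyll synthesis genes was 0.789. DREB and related AP2 genes had a median of 0.78 over 9 genes (adjusted p = 0.0606), with 2 called higher, and 5 higher and 2 lower when adjusted over the list alone. The list gained a call with no filter (0.0278), equal 75th percentiles (0.0265) or scaling to the spike-ins (3.98e-14), but with an estimated correlation its adjusted p was 0.789. Scaled to the spike-ins its median was 0.67, no larger than before. DREB1B and DREB1A stood at 3.06 and 1.81 without passing. Dehydrin and LEA genes had a median of -0.40 (adjusted p = 0.0947) and defence genes one of -0.53 (adjusted p = 0.145). Both gained calls when scaled to the spike-ins (adjusted p = 0.0125 and 3.50e-06), and with an estimated correlation stood at 0.826 and 0.804. Scaled to the spike-ins their medians were -0.39 and -0.54 relative to all genes, about as before, so the gained calls add no evidence. Clock genes (0.18) and root marker genes (0.13) were not called as lists.

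In all, 271 probe sets changed at 20 min, 226 higher and 45 lower, and 246 of them at least 2-fold. At least 2-fold changes the same way in both genotypes numbered 428 higher and 131 lower, where independent pairs would give 59.1 and 17.2. The salt changes of the genotypes correlated at 0.385 across probe sets. The count of calls rests on the variance trend of limma, without which it was 0, with 3103 probe sets at an unadjusted p under 0.05. It was 44 without the nontransgenic array from before treatment and 27 without the transgenic one, and scaled to the spike-ins, which shifted the all-gene median to -0.10, it was 453 higher and 295 lower (60.6% higher against 83.4%).

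**Figure D1:**
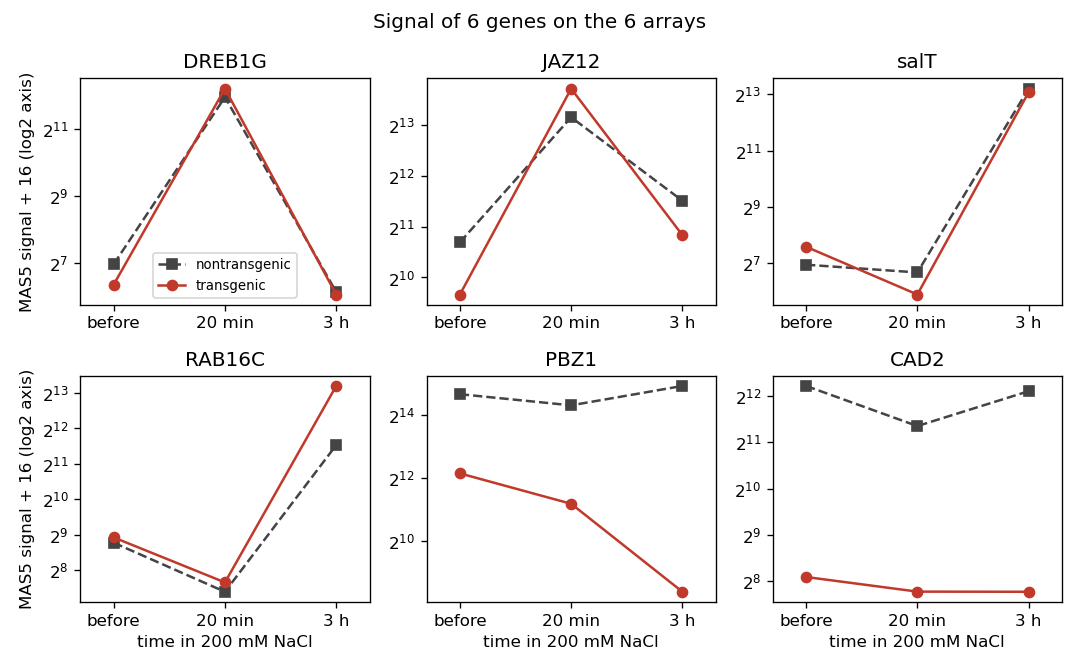
MAS5 signal plus 16 on a log2 axis for 6 genes against time in 200 mM NaCl, with 1 point per array (squares and dashed lines nontransgenic, circles and solid lines transgenic). DREB1G and JAZ12 peak at 20 min, salT and RAB16C are highest at 3 h, and PBZ1 and CAD2 are lower in transgenic leaves at every stage.

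The 3 h comparison asks which transcripts differed after longer exposure. The lectin gene salT and the dehydrin genes RAB16C and RAB16B rose, and the expansin genes EXPB3, EXPA2 and EXPB6 fell. The signal of salT (LOC4326471) rose by 5.88 ± 0.32 (adjusted p = 0.00198), from 106.6 to 9396 in nontransgenic and from 174.8 to 8605 in transgenic leaves. RAB16C (LOC4350452) and RAB16B (LOC4350453) rose by 3.52 ± 0.36 and 2.75 ± 0.16 (adjusted p = 0.00628 and 0.00210). EXPB3, EXPA2 and EXPB6 fell by 3.03 ± 0.45, 2.40 ± 0.29 and 2.24 ± 0.49 (adjusted p = 0.0159, 0.00906 and 0.0497).

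ICL, at -1.60 after 20 min without a call, rose by 4.22 ± 0.37 at 3 h (adjusted p = 0.00430). SMR1 rose by 3.24 ± 0.30, PPT2 by 2.83 ± 0.21, the lectin-like gene R40C1 by 2.77 ± 0.50 and the tonoplast aquaporin gene TIP3;1 by 2.77 ± 0.42. Their adjusted p was 0.00500, 0.00292, 0.0291 and 0.0179. Among falls, the actin-depolymerizing factor gene ADF11 fell by 2.22 ± 0.16 (adjusted p = 0.00282) and the cytokinin response regulator gene RR2 by 2.32 ± 0.26 (adjusted p = 0.00734). The glutaredoxin gene GRXC15 fell by 2.47 ± 0.48, and 4CL2 and EXO1, whose signals at 3 h were below 16, fell by 2.49 ± 0.37 and 2.19 ± 0.36. Transgenic signals of EXPB6 at 3 h (10.4) and of TIP3;1 before treatment (8.31) were below 16 as well, so the size of these changes depends on the offset. All were changed the same way in both genotypes, as the naming rule required. R40C1, GRXC15, 4CL2, EXO1 and EXPB6 lost their calls with no filter, at adjusted p between 0.0522 and 0.115, and EXPB6 with an offset of 1 as well (0.0734).

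Dehydrin and LEA genes were the list called at 3 h, with a median of 1.95 over 8 genes (adjusted p = 1.05e-04), and 0.884 with an estimated correlation. Of these genes 4 rose, and 7 when adjusted over the list alone. Besides RAB16C and RAB16B, the embryo-type gene Emp1 rose by 2.20 (adjusted p = 0.0462), while RAB16D at 2.63 did not pass. The list's median was 1.71 in nontransgenic and 1.92 in transgenic leaves. Salt response genes had a median of 0.56 over 11 genes (adjusted p = 0.0640), with 3 called higher and 1 lower, and 6 and 2 adjusted over the list alone; RAB21 rose by 1.56 and TPP1 fell by 1.97. This list gained a call with no filter (0.0479), equal 75th percentiles (0.0325) or scaling to the spike-ins (1.36e-05), and stood at 0.884 with an estimated correlation. The zeaxanthin epoxidase gene ABA1 rose by 1.32 (adjusted p = 0.00638), and ABA8OX1 stood at 0.46.

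Protein phosphatase genes PP2C59, PP2C51, PP2C30 and PP2C11 rose by 2.17, 1.76, 1.63 and 1.57, with 5 of 52 higher and 1 lower, and 8 and 1 when adjusted over the list alone. Aquaporin genes went both ways, as TIP4;1 and PIP2;7 rose by 1.74 and 1.44 and Lsi6 fell by 2.10. Of 36 cell wall genes, 5 fell and none rose, while 6 fell and 3 rose when adjusted over the list alone. The list was not called (adjusted p = 0.542, median -0.02, mean -0.27), but was when scaled to the spike-ins (0.0335), and stood at 0.884 with an estimated correlation; EXPB4 fell by 1.89. HSFA3, HSFB2B and HSP17.9A rose by 1.94, 1.47 and 1.43. IAA13 rose by 2.52 and PIN5A fell by 1.28. The kinase gene CIPK10 rose by 2.07 and CIPK21 fell by 1.20. GA20OX3 rose by 1.62, the potassium channel gene AKT1 by 1.15 and the chitinase gene Cht3 by 1.63. The nitrogen genes parted, with GLN1;2 down (-1.73) and GLT2 up (1.68). Osmolyte genes had a median of 0.21 but a mean of -0.25 and a set test of negative sign that was far from a call (adjusted p = 0.828), with TPP7 falling by 1.30. In the chlorophyll list, PORB rose by 0.79 while GluTR fell by 1.04 and HEMB by 0.76. Jasmonate genes had a median of -0.12 and a mean of 0.04 at 3 h; JAMYB rose by 1.15.

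Of 7 clock genes, 2 rose and 1 fell, and 4 and 1 when adjusted over the list alone. GI rose by 2.13 and PRR37 by 0.87 (adjusted p = 0.00703 and 0.0113), and LHY fell by 1.42 (adjusted p = 0.00364). The list was not called (median 0.46, adjusted p = 0.114). Altogether 1722 probe sets changed at 3 h, 984 higher and 738 lower, and 1039 of them at least 2-fold. At least 2-fold changes the same way in both genotypes numbered 646 higher and 387 lower, where independent pairs would give 111 and 60.7. Without limma's variance trend the count of calls was 0, with 5536 probe sets at an unadjusted p under 0.05. It was 543 without the nontransgenic array from before treatment, 372 without the transgenic one and 961 without the transgenic 3 h array.

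The genotype comparison asks how antisense-OsPDCD5 leaves differed from nontransgenic leaves over the 3 stages. Defence genes were lower as a list in transgenic leaves (camera adjusted p = 1.66e-04), a call lost with an estimated correlation (0.778). Among named genes, pinA, CYP76M7, PAL06 and AT5 had the largest negative differences. The autophagy gene ATG8D, the heat shock gene HSP16.0 and the methyl-donor gene METK3 were higher. The zinc finger gene OsC3H40 (LOC4340263) was higher by 7.17 ± 0.25 (adjusted p = 3.08e-05), with a signal of 2.23 to 22.2 in nontransgenic and 3872 to 4236 in transgenic leaves. The gene pinA (LOC9268662) was lower at -6.57 ± 0.26 (adjusted p = 5.51e-05), with 15773 to 26185 in nontransgenic and 141.2 to 253.9 in transgenic leaves. The cinnamyl alcohol dehydrogenase gene CAD2 was lower (adjusted p = 5.97e-05), with signals of 2591 to 4729 in nontransgenic and 203.3 to 257.4 in transgenic leaves.

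The autophagy gene ATG8D was higher by 5.52 ± 0.31 (adjusted p = 1.63e-04), HSP16.0 by 5.40 ± 0.39 (adjusted p = 4.31e-04) and the S-adenosylmethionine synthase gene METK3 by 5.34 ± 0.20 (adjusted p = 4.89e-05). Nontransgenic signals of these genes lay between 6.28 and 37.3 and those of OsC3H40 between 2.23 and 22.2, near or below the offset, on which the size of these differences depends. The diterpene cyclase gene KSL7 was higher by 3.88 ± 0.51, BURP2 by 3.25 ± 0.55, CRSH2 by 2.63 ± 0.42 and PHP5 by 2.34 ± 0.14. Lower in transgenic leaves were the diterpenoid oxidase gene CYP76M7 (-5.29 ± 0.41), the phenylalanine ammonia-lyase gene PAL06 (-4.84 ± 0.37) and the acyltransferase genes AT5 (-4.63 ± 0.36) and AT4 (-4.16 ± 0.40). Transgenic signals of AT4 (1.22 to 28.5) and PAL06 (20.6 to 28.8) lay near the offset, on which the size of these differences depends. The trypsin inhibitor gene RBTI and PBZ1, a pathogenesis-related gene, were lower at -4.25 ± 0.62 and -4.05 ± 0.70. The adjusted p of these genes lay between 2.28e-04 and 0.00984, and each differed the same way at all 3 stages, as the naming rule required.

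Of 20 defence genes, 11 were lower and 1, KSL7, higher, and 14 and 1 when adjusted over the list alone. Their median was -1.44 (adjusted p = 1.66e-04, and 0.778 with an estimated correlation). It was -1.31 at 20 min and -1.68 at 3 h, and smaller in size before treatment than at either time. Chlorophyll synthesis genes had 11 of 14 higher and none lower, also when adjusted over the list alone, with a median of 0.55 (adjusted p = 1.64e-06, and 0.778 with an estimated correlation). Scaling to the spike-ins shifted the all-gene median to -0.51 and that of chlorophyll genes to -0.01, which was 0.50 above all genes, and the list kept its call (adjusted p = 0.0109). PPO was higher by 1.26, CHLG by 0.95, CHLD by 0.76 and PORB by 0.75. Of 23 cytosolic ribosome genes, 12 were lower and 2 higher, and 15 and 2 when adjusted over the list alone, with a median of -0.39 (adjusted p = 0.00362), RPL30 at -0.86 and RPL18 at 1.32. Proteasome genes had 6 of 19 lower, also when adjusted over the list alone, and a median of -0.23 (adjusted p = 0.0246), with PAE1 at -0.56. With an estimated correlation the adjusted p of both lists was 0.778. Scaled to the spike-ins they lost their calls (adjusted p = 0.413 and 0.428), although their medians relative to all genes, -0.44 and -0.28, were about as large. Of 36 cell wall genes, 11 were lower and 1 higher, and 15 and 1 when adjusted over the list alone, with a median of -0.50 (adjusted p = 0.0377, 0.0955 with no filter, 0.0528 with the mean over probe sets and 0.778 with an estimated correlation). EXPB3, XTH8, EXPB4 and CESA1 had log2 values of -2.81, -2.79, -2.51 and -2.01.

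Clock genes had a median of 0.38 (adjusted p = 0.0246), osmolyte genes 0.31 (adjusted p = 0.0377) and photosystem and antenna genes 0.25 (adjusted p = 0.0428). With an estimated correlation the adjusted p of each was 0.778. Scaled to the spike-ins their medians were -0.18, -0.23 and -0.31, still above all genes by 0.33, 0.28 and 0.20, but without a call (adjusted p = 0.243, 0.163 and 0.455). Osmolyte genes also lost their call with the mean over probe sets (0.121), an offset of 1 (0.0807) and no filter (0.0524), and photosystem genes with that mean (0.0581), quantile normalization (0.231) and equal 75th percentiles (0.0605). TPP10 and TPP9 were higher by 1.44 and 1.29, and PRR37 by 0.40. Jasmonate genes had 7 of 31 lower and none higher, also when adjusted over the list alone, with a median of -0.19 (adjusted p = 0.0661, and called with no filter at 0.0408 or quantile normalization at 0.0425, but 0.778 with an estimated correlation), and LOX9, OPR5 and LOX8 stood at -2.38, -2.09 and -1.57. In the cell death list, to which ATG8D belongs, 4 of 21 genes were higher and 4 lower, also when adjusted over the list alone, with a median of -0.03 and a mean of 0.19. LOL4 was higher by 0.91, while LOL2 and VPE1 were lower at -0.77 and -0.74. Root marker genes had a median of -0.85 (adjusted p = 0.341), with NAS1 and NAS2 lower at -1.65 and -1.03.

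Single genes of other groups also differed. NAC45 was lower at -3.69 (adjusted p = 7.69e-05), the gibberellin pathway gene KAO at -2.79, the aquaporin gene NIP1;1 at -2.16 and the peroxiredoxin gene PRXIIE-1 at -1.87. WRKY62 was lower at -1.58, HSP16.9B at -2.04 and HSFA4D at -1.53, and the calcium-binding gene CML14 at -1.72. GSTF1 was higher by 1.22 and GSTF2 lower at -1.27. The dehydrin genes parted, with rab25 at -3.07 and Emp1 at -1.78 but RAB16B at 1.14; the list's median was 0.43 and its mean -0.20. The kinesin gene KIN14K was higher by 1.72 and the auxin carrier gene PIN5A by 1.21.

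**Figure D2:**
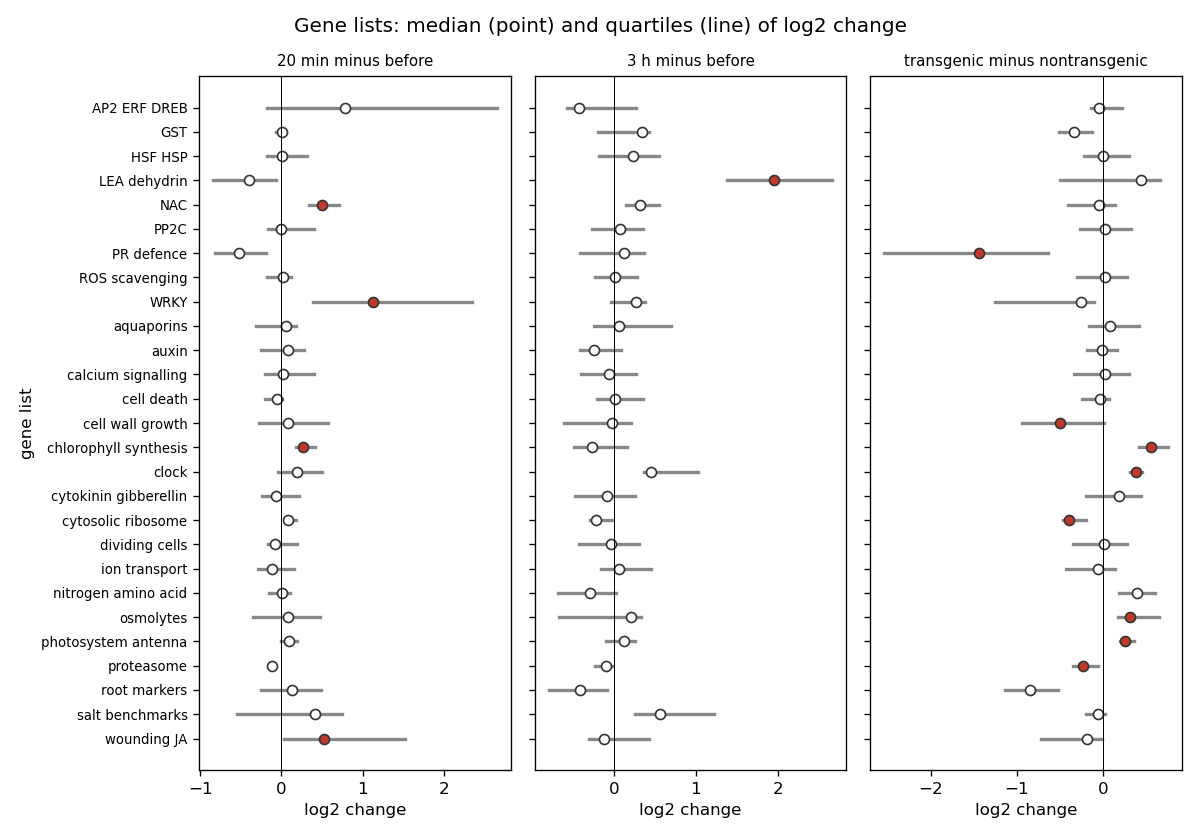
Median (points) and quartiles (lines) of log2 change for the 27 set-tested gene lists in each comparison, with filled points where the camera adjusted p was under 0.05. Dehydrin and LEA genes stand at 1.95 at 3 h and defence genes at -1.44 in transgenic leaves, on the authors' scale; scaled to the spike-ins, the medians of clock, osmolyte, photosystem and chlorophyll genes on the right fall below 0 with all genes but stay above the all-gene median.

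Between the genotypes 5889 of 28629 probe sets (20.6%) differed, 2845 higher and 3044 lower in transgenic leaves, and 2562 of them at least 2-fold. The count was 3054 and 2999 without the nontransgenic and transgenic arrays from before treatment, 3489 and 3455 without those at 20 min, 3151 without the variance trend and 2430 without the time block. At least 2-fold differences the same way at all 3 stages numbered 594 higher and 912 lower, where independent pairs would give 7.38 and 14.6. The genotype differences at single stages correlated at 0.682 to 0.758 across probe sets. Such repeats over the stages do not tell the transgene from any other lasting difference between the 2 sets of seedlings. The 36 poly-A spike-in probe sets were 0.56 higher on the log2 scale on transgenic arrays, and the 5′ minus 3′ signal of GAPDH was -1.68 against nontransgenic arrays, with -0.44 for actin, -0.07 for ubiquitin and -0.00 for cyclophilin. Scaling to the spike-ins gave 841 probe sets higher and 11097 lower.

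The last comparison asks whether NaCl moved genes differently in transgenic leaves, and its differences were not tested. At 20 min DREB1B had a log2 response of 1.51 in nontransgenic and 4.60 in transgenic leaves, DREB1A 0.54 and 3.08, WRKY76 0.39 and 3.12 and JAZ9 0.66 and 3.17. All 4 had lower signals in transgenic leaves before treatment. CPS2 had responses of -4.48 and -1.56. In the other direction, the vacuolar transporter gene VIT2 had responses of 3.03 in nontransgenic and -1.92 in transgenic leaves, GSTU1 0.58 and -2.49, Cht8 0.72 and -1.95, WOX11 1.68 and -0.83 and the germin-like gene GER5 2.48 and 0.25. Dehydrin and LEA genes had a median of 0.24 in nontransgenic and -1.13 in transgenic leaves at 20 min, and the median of their differences, -1.35, lay below the range of random lists. At 3 h that median was 0.37, above the range. Such differences put 7 of 27 lists outside the 95% range at 20 min and 12 at 3 h, so lying outside it does not set a list apart. Signals of CPS2, VIT2, WOX11 and GER5 reached near or below the offset, and with an offset of 64 their differences were 1.58, -3.60, -1.18 and -1.27.

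At 3 h the glutaredoxin gene GRXC10 had responses of -2.48 in nontransgenic and 1.80 in transgenic leaves, SDS -1.14 and 2.47, RBTI 0.56 and 3.48, LOX8 -0.99 and 1.46 and HSFB2C 0.63 and 2.99. Conversely PBZ1 had responses of 0.26 and -3.75, CPS2 -0.18 and -4.14, CYP71Z7 0.45 and -3.32, LAC24 2.10 and -1.65 and BURP2 2.49 and -0.89. With an offset of 64 the difference was 1.95 for SDS, -2.64 for CPS2 and -3.06 for CYP71Z7. Aquaporin genes had medians of 0.30 and -0.16, and the median of their differences was -0.60, below the range of random lists as for others of those 12. Over all tested probe sets the difference of responses had an SD of 0.61 at 20 min and 0.69 at 3 h. At least 4-fold more positive and more negative responses in transgenic leaves numbered 155 and 178 at 20 min and 175 and 313 at 3 h.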

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

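The tests of RNA integrity, of the hours passed, of handling and of clock genes were chosen after the results were seen. Differences between genotypes in the salt response were not tested, since each group was 1 array.

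Several named genes had responses of opposite sign in the 2 genotypes. At 20 min the response in transgenic leaves minus that in nontransgenic leaves was -4.94 for VIT2, -3.07 for GSTU1, -2.67 for Cht8 and -2.51 for WOX11. At 3 h it was 4.28 for GRXC10, 3.61 for SDS and 2.45 for LOX8, and -4.01 for PBZ1, -3.77 for CYP71Z7, -3.75 for LAC24 and -3.38 for BURP2. The medians of defence genes at 3 h went apart by -0.92 and those of root marker genes at 20 min by -1.20, while the medians of the members' own differences were -0.45 and -1.16. Each genotype's median lay outside the range of random lists, with opposite signs, but so many of the 27 lists lay outside it (12 and 11 at 20 min, 10 and 8 at 3 h, nontransgenic and transgenic) that this alone does not set a list apart. Signals of VIT2, WOX11 and SDS reached near or below the offset, and their differences were -7.22, -4.12 and 5.29 with an offset of 1 and -3.60, -1.18 and 1.95 with 64. That of CYP71Z7 was -3.06 with an offset of 64.

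Control probe sets outside the comparisons also differed with genotype. The poly-A spike-ins were higher by 0.56 on the transgenic arrays, and the 5′ minus 3′ signal of GAPDH was lower there (-1.68).

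The first pattern weighed was the at least 4-fold differences between genotypes, such as OsC3H40, METK3, CAD2 and pinA. A difference in scaling as the whole cause was argued against, since it moves all probe sets the same way while 282 were higher and 523 lower. Scaled to the spike-ins, 89.7% of these 805 probe sets stayed at least 4-fold, but that share was largely set by their starting sizes and decides little. The lower ones could only stay under that shift, as could the higher ones furthest above 4-fold. Of the higher ones 70.6% stayed and the other 83 remained called. The median log2 difference of these 83 went from 2.14 (quartiles 2.06 and 2.26) to 1.68 (1.60 and 1.79). RNA degradation could not be told apart, as the 5′ minus 3′ difference had a median of -0.26 over 4 control genes that ranged from -1.68 to -0.00. Differences of sequence between the lines may play a part, since a gene's other probe set showed 0.421 of the called log2 difference (95% interval 0.270 to 0.569, 64 genes) against 0.677 (0.566 to 0.805, 16 genes) for NaCl at 3 h, but the intervals met. Called genes within 100 kb to 1 Mb of each other formed 415 pairs, above the shuffled 95% range of 313 to 406. That was 1.17 times the shuffled mean (0.881 for NaCl at 3 h), short of the excess over NaCl set beforehand. A background that differs in blocks was thus left open, and the antisense transgene is the untested biological explanation.

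The genotype count of 5889 came from 1 of 10 splits of the arrays, too few for a share under 0.05. The highest count from another split was 0, with 177 to 812 probe sets at an unadjusted p under 0.05. Every other split mixes the genotypes, so their difference enters its error and lowers its count. The 0 therefore does not set the genotype split apart. Of the 10 splits, 4 part the arrays of every stage, and those of them that mix the genotypes gave 177, 196 and 432 such probe sets.

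The second pattern was the rise of jasmonate genes such as JAZ12 and JAZ13 at 20 min. Its call as a list was lost with an estimated correlation (adjusted p = 0.789). That test, with very few degrees of freedom, gave 0 lists at an unadjusted p under 0.05 in any contrast. The loss therefore cannot decide whether the list is firm. JAZ13 lost its own call with an offset of 1, no filter or quantile normalization (0.0513 to 0.0855). Scaling between arrays as a shift of all genes was argued against, since the all-gene median was 0.01 beside the list's 0.52. After quantile normalization the list's median was 0.50 and the all-gene median -0.03. So small a move could not have removed the rise, and the value after quantile normalization decides nothing. A trend with the hour that goes on to 3 h was argued against as well, since the 3 h minus 20 min change had a median of -0.50 over 31 genes (two-sided sign-flip permutation p = 1.2e-04 across genes, which are not independent replicates). The list was picked for its rise at 20 min and its 3 h values were known, so that p-value overstates the evidence. A passing change with the hour was not addressed. Handling during transfer, for which 7 called members give no measure, cannot be told apart from NaCl, since no group was moved without it.

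The third pattern was the change of clock genes at 3 h. The hour cannot be told apart from NaCl as its cause, because no untreated seedlings were sampled at 3 h. All 8 changes of LHY, GI, PRR1 and PRR37 in the 2 genotypes went from a morning to a midday state, by 0.69 to 2.60, but these genes and directions were chosen after their values were seen, and PRR1 was not called (adjusted p = 0.124), so the count decides nothing.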

How the results depend on the processing

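Counts of calls depended on the variance model most plainly for NaCl. Without the trend, calls fell from 271 to 0 at 20 min, from 1722 to 0 at 3 h and from 5889 to 3151 for genotype. Without the genotype block they were 0 (1319 at an unadjusted p under 0.05) and 1, and without the time block 2430, as block differences then entered the error. With no filter they were 152 and 992 for NaCl, and 150 at 20 min among the brightest probe sets alone. Scaling to the spike-ins gave 748 at 20 min and 11938 for genotype, 241 and 3866 of them the same probe sets. Named genes and lists that gained a NaCl call under this scaling changed by about as much as before, relative to all genes. Those gains are not added evidence. Leaving out 1 array gave 27 to 761 at 20 min, 372 to 2130 at 3 h and 2999 to 6082 for genotype, and leaving out both 20 min arrays 3498. At 20 min the count was 147 without the transgenic 20 min array, 761 without the nontransgenic 3 h array and 707 without the transgenic one. For genotype it was 3054 and 2999 without the nontransgenic and transgenic arrays from before treatment, and 3489 and 3455 without those at 20 min. Changes of at least 2-fold in both genotypes went from 559 to 343 with an offset of 64 and 960 with no filter at 20 min, and from 1033 to 668 with an offset of 64 at 3 h. With an estimated correlation the called lists went from 4, 1 and 8 to 0, with 0 at an unadjusted p under 0.05. That test has very few degrees of freedom, so a call lost there does not decide whether a list is firm. Every called list but NAC (-0.03) and cell wall genes (-0.01) had an estimated correlation above the preset 0.01. It was 0.61 for chlorophyll synthesis, 0.73 for WRKY, 0.44 for dehydrin and LEA and 0.095 for defence genes. Those estimates rest on 2 residual degrees of freedom, but the camera p-values at the preset may be too small. Beyond these constructions the cause was not tested.

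Among the named genes and set-tested lists, no called change was called in the other direction under the settings applied to them. The genotype median of chlorophyll genes nevertheless went from 0.55 to -0.01 when scaled to the spike-ins. Of the alternative values of named gene changes, 268 kept their side of the threshold, 13 lost and 6 gained a call, and of list changes 537 kept it, 14 lost and 16 gained one. That tally leaves out the estimated correlation, under which all 13 called lists lost theirs. Named genes and lists were not evaluated without the variance trend, among the brightest probe sets, or without probe sets that can bind several transcripts. Fits without a block or with an array left out were not applied to them either. Without the trend 0 probe sets were called for NaCl, so no named NaCl change kept its call there. The alternatives planned for OsPDCD5 were not run. Signal over background limits dim genes: 32.9% to 37.7% of probe sets per array had a log2 signal below 4.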
